A study of Homo sapiens with 8 samples.

How the data were processed

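Long RNA was measured in 8 libraries of HEK293 cells, 4 transfected with a mimic of the 3' tDR of tRNA-Asp-GTC and 4 with a scrambled mimic, each at 50 nM with a lipid reagent and collected 48 hours later. Per the labels' protocols, total RNA was extracted with TRIzol and made into libraries with a stranded low-input kit for mammalian total RNA (SMARTer Pico, version 2). The authors deposited 1 table of whole-number read counts per gene, with 1 column per library and no normalization. Per the submitters' processing notes, cutadapt 2.10, STAR 2.7.8a, FastQC 0.11.9, featureCounts 2.0.2 and DESeq2 1.30.1 were used with the builds GRCh38.p13 and hg38, with no role or setting given for any tool. The strand setting, the annotation release, the counting over exons or whole genes, the treatment of reads that fit several places and any use of molecular identifiers are not given in the sources used here. Counts of overlapping, antisense and near-identical genes are therefore uncertain for each single gene.

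The table held 60606 genes, of which 25964 had 0 counts in all libraries, and each of its columns matched 1 library by name. GENCODE release 29 on GRCh38 gave positions, spans and gene types for 57081 of the genes (94.2%, holding 99.7% of counts), and 20417 genes were named by an identifier alone. Coordinates are 1-based. Counts were compared between all pairs of libraries by a chi-square statistic over genes, and each pair differed by more than counting noise (2.20 to 9.32 per degree of freedom). Libraries made from the same RNA can also exceed that noise, so this does not show whether the libraries are separate samples. In a principal component analysis of log2 CPM the first component held 39.6% of the variance and separated the groups. No sequencing batch or date is given in the labels.

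The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 for gene lists, on all 8 libraries with group as the only term. TMM factors scaled the libraries and edgeR's own filter on low counts was used, which left 17184 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.00446. Levels are given as CPM with TMM-scaled library sizes, as mean ± SD of 4 libraries, and fold changes as log2 of tDR over control with their SE. The steps were tested on simulated counts for the same 17184 genes with 50 genes changed at each of 4 fold sizes. They recovered 50% of genes changed 1.3-fold, 62% of those changed 1.5-fold, 80% of those changed 2-fold and 92% of those changed 3-fold. Of the calls 2.07% were false, and 0 of 30 unmoved gene lists were called. The simulated genes were drawn independently of each other, with no background and no trend with expression, length or GC content. The simulation therefore does not show how often false calls arise in real libraries, where genes are correlated and such trends exist.

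Before the data were examined, 38 gene lists were fixed to fit transfected kidney-derived cells, small RNA mimics, hypoxia, autophagy and histone mRNA. Of their 703 entries 702 were found. The histone list was put first from knowledge of the study, in which this tDR is studied with histone mRNA and autophagy of RNA. That list was therefore not chosen blind to the subject of the study. The union of the replication-dependent histone lists was tested first and 27 other lists after it. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over 36 lists, with camera at an estimated correlation and fry, which asks whether the genes move 1 way without comparing them with other genes, beside it. Counts of called members are from the test over all genes unless said to be adjusted over the list alone. Each list median was also compared with 10000 random lists matched on mean expression. Single values per library, such as the histone share, were compared by exact two-sided permutation tests over the 70 assignments of 8 libraries to 2 groups of 4. The smallest p these can give is 0.0286.

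The genes named in the text follow a rule set at the same time: among called genes with a gene symbol, the 10 higher and the 10 lower with the smallest p and the 5 higher and 5 lower with the largest change among those with mean log2 CPM above 2, up to 4 members of each list with the smallest p, and PUS7, SLBP, SQSTM1 and MAP1LC3B. From most lists fewer than 4 members are named with values, those with the smallest p except for 1 gene that is not reported here, which gave 100 genes. ULK1, TAX1BP1, ATG12, COL4A2 and H4-16 fall outside the rule and are named because they complete a count; they were chosen after their values were seen. Genes that did not pass are given as values.

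Background was estimated after the data were seen. The counts over 381 olfactory receptor genes (2478 kb of gene span) gave a density for each library, and this density times a gene's span gave that gene's expected background. Whether reads were counted over whole genes or over exons alone is not given. If over exons alone, this estimate could overstate the background of long genes, and all values that use it depend on this. The depth limits what single libraries show: 3 counts, the most that a count of 0 allows, correspond to 0.284 CPM in the deepest and 0.513 CPM in the shallowest library. Intervals on shares of counts are Wilson 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

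Alternatives fixed in advance were DESeq2's size factors, library size alone, factors computed without mitochondrial, ribosomal, short noncoding and histone genes, no filter, a filter of at least 10 counts in 4 libraries, the replicate number as a block, a loess correction (span 0.4) for gene span and GC content with and without the block, DESeq2 1.42.0, limma voom, a minimum fold of 1.2, an adjusted p under 0.1, other set tests and leaving out each library in turn. Subtracting the background and keeping the 11816 genes with under 10% background were added after seeing the data. Tested genes without a span in GENCODE release 29 were given a background of 0, so they count among the 11816 and nothing was subtracted from them. Of the 11816, 11332 had a span. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. GC content was that of the longest annotated transcript of each gene, taken from GENCODE release 29, and the correction for span and GC content, called length and GC correction here, covered 16700 of the tested genes (97.2%).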

Results

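Total RNA was sequenced from HEK293 cells, an established line derived from human embryonic kidney, after transfection with a synthetic small RNA. The treated cells received a mimic of the 3' fragment of tRNA-Asp-GTC, which belongs to the tRNA-derived RNAs (tDRs). The control cells received a scrambled mimic. Both mimics were given at 50 nM, and the cells were collected 48 hours later. Each group held 4 libraries, measured as read counts per gene. Total counts were 9374886, 8432736, 6536554 and 10557740 in control replicates 1, 2, 3 and 4, and 5848305, 7142701, 7519204 and 9237986 in tDR replicates 1, 2, 3 and 4. The comparison asked which long RNAs differ between cells given the tDR and cells given the scramble. The title of the series places this tDR in the response to hypoxia, in protection of the kidney and in autophagy of RNA. The labels do not say whether the libraries came from separate cultures, so p-values measure the spread between these 8 libraries, which may be technical.

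Replication-dependent histone mRNAs, which encode the histones placed on newly copied DNA, were lower in the cells given the tDR. Of 46 such genes tested, 36 fell and 10 did not pass the test, and the median log2 fold change of the 46 was -0.60, a level 34.1% lower. Genes for ribosomal proteins, for the nuclear-encoded respiratory chain, for heat shock proteins and for the G2/M phase also fell as lists, with smaller medians between -0.20 and -0.24. With a correlation between genes estimated from the data neither these lists nor the histone list was called, and after correction for gene length and GC content the heat shock list was not called. NEAT1, the long noncoding RNA that scaffolds paraspeckles, rose 1.79-fold. The transcription factor genes RELB, EGR1, ETV5 and ATF3 rose as well. Of 30 autophagy genes 4 rose, OPTN and SQSTM1 among them, and 3 fell, TAX1BP1 among them. The autophagy list was not called (camera, Benjamini-Hochberg adjusted p = 0.712). Over all 17184 genes tested, 2206 were higher and 1962 were lower in the tDR libraries (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Many of the higher calls were in genes whose counts may be largely background. Of genes with over 50% estimated background 870 were higher and 1 lower. With background subtracted, 2057 of the 4168 called genes kept their call and direction. Scaling to library size alone gave 3295 higher and 907 lower.

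All 5 classes of replication-dependent histone contributed. The 3 tested H1 genes, which encode linker histones, all fell, with a median log2 fold change of -0.73. H1-4 (chromosome 6, 26156354 to 26157107) went from 1016 ± 60.9 CPM in controls to 614 ± 38.3 CPM with the tDR (SD, n = 4). Its log2 fold change was -0.73 ± 0.046 (SE, edgeR, Benjamini-Hochberg adjusted p = 1.34e-18). CPM of single genes use TMM-scaled library sizes. H1-2 went from 803 ± 50.9 to 495 ± 19.1 CPM and H1-3 from 75.3 ± 8.83 to 43.6 ± 0.606 CPM. Of the 12 tested H2A genes 11 fell, with a median of -0.63. H2AC20 (chromosome 1, 149886975 to 149887364) went from 324 ± 18.2 to 188 ± 11.6 CPM, a log2 fold change of -0.78 ± 0.051 (SE; edgeR, Benjamini-Hochberg adjusted p = 2.06e-18), and H2AC16 fell by 0.76. Of the 13 tested H2B genes 11 fell, with a median of -0.56; H2BC4 fell by 0.73, H2BC11 by 0.72, H2BC5 by 0.70 and H2BC18 by 0.66 on the log2 scale. Among H3 genes 5 of 8 fell, with a median of -0.53, and H3C2 fell by 0.68. Among H4 genes 6 of 10 fell, with a median of -0.46; H4C2 fell by 0.75 and H4C3 by 0.69. After correction for gene length and GC content the median of all 46 shrank to -0.40 and those of the H1, H2A, H2B, H3 and H4 genes to -0.54, -0.43, -0.36, -0.32 and -0.24, and each list was still called by camera with its preset correlation. With an estimated correlation and no such correction none of the 5 classes was called (camera, Benjamini-Hochberg lowest adjusted p = 0.0944). Histone genes are near-identical copies of each other, and how reads that fit several copies were counted is not given in the sources used here, so the value of any single copy is uncertain while their sum is less so.

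**Figure D1:**
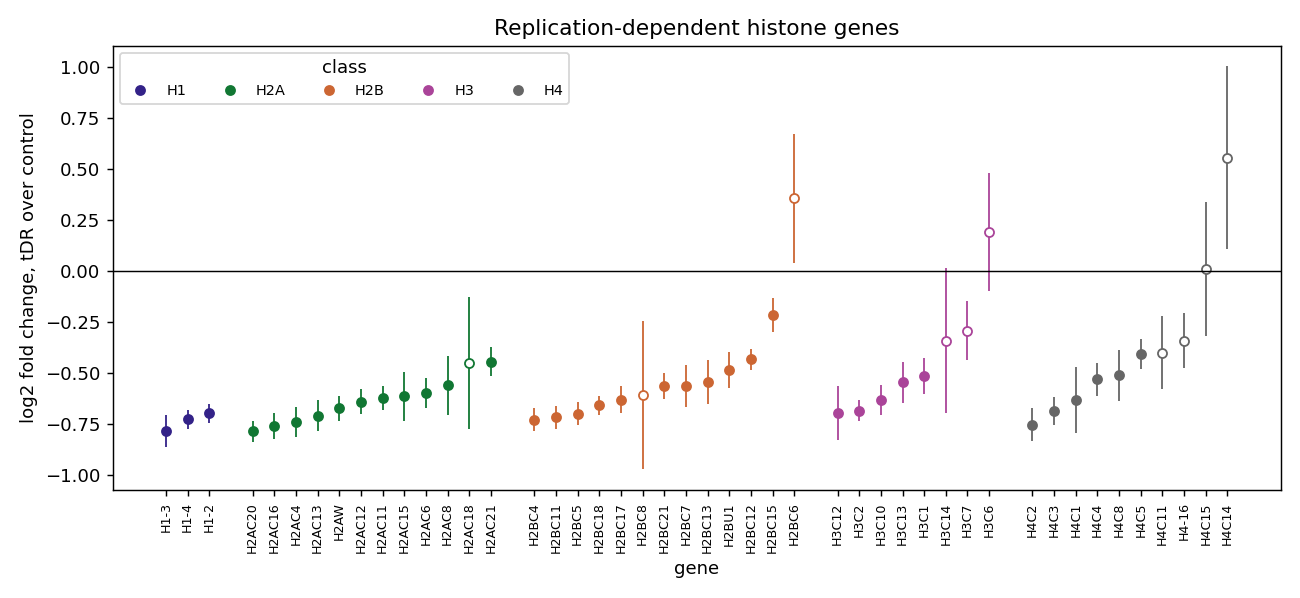
Log2 fold change, tDR over control, of the 46 tested replication-dependent histone genes, grouped by class along the x axis. Points are edgeR estimates and bars their SE; filled points passed the test at an adjusted p under 0.05 (36 genes, all below 0) and open points did not (10 genes, 4 of them above 0).

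Most of the tested histone genes lie in the clusters of chromosome 6, where 29 of 34 genes between 26020490 and 27893843 fell, with a median of -0.63. On chromosome 1, 7 of 11 fell, with a median of -0.49, and the single gene on chromosome 12, H4-16, had a log2 fold change of -0.34 and did not pass. In 31 of the 46 genes each tDR library lay below each control library. For a gene with no group difference, chance gives this in 1.43% of cases. The groups differed in 4168 genes and the histone genes move together (estimated correlation 0.263), so that rate is no test of the list. The 10 genes that did not pass were low: their median control level was 3.10 CPM and their highest 19.7 CPM. Summed over the 68 annotated histone genes found, the histone share of all counts went from 0.617% ± 0.0326 to 0.416% ± 0.0146 (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest that 70 assignments can give). The lowest control library, replicate 1, held 0.571% (Wilson 95% interval 0.566% to 0.576%), and the highest tDR library, also replicate 1, held 0.438% (0.433% to 0.443%). Adjusted over the list alone, 38 of the 46 genes passed. The histone list was called by camera with a preset correlation (Benjamini-Hochberg adjusted p = 2.55e-21) and by fry (adjusted p = 0.000388), but not when the correlation between its genes was estimated from the data (camera, Benjamini-Hochberg adjusted p = 0.0944 with an estimated correlation).

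**Figure D2:**
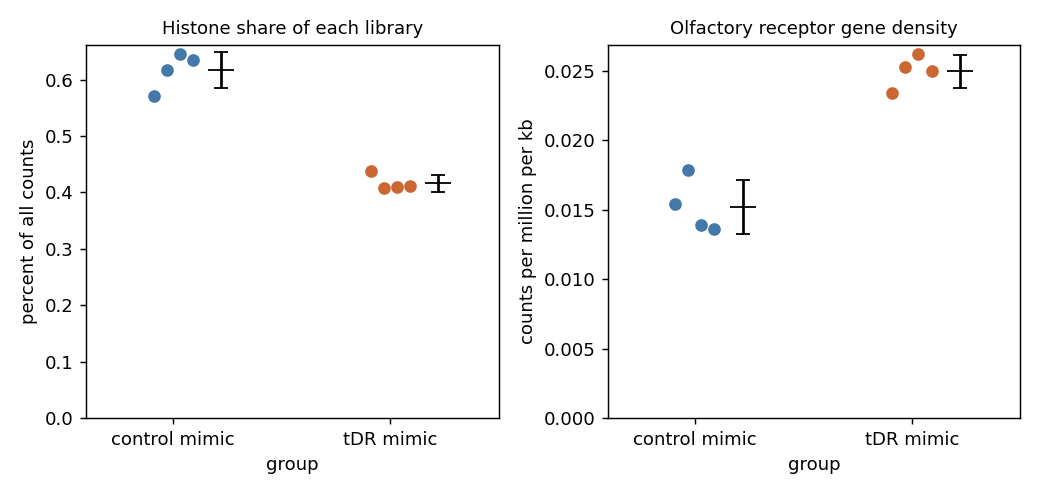
Left, share of all counts on replication-dependent histone genes in each library, in percent; right, count density over 381 olfactory receptor genes, in CPM per kb. Points are libraries and bars the mean ± SD of 4; on both axes the groups do not overlap, with histone shares of 0.571% to 0.645% in controls and 0.407% to 0.438% with the tDR.

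Histone variants, histone mRNA factors and pseudouridine synthases had list medians of smaller size than that of the replication-dependent histones. In each of these lists most members did not pass. Of 10 replication-independent histone variants, 4 fell, among them H2AZ1 (log2 fold change -0.30) and H3-3B (-0.18). After correction for gene length and GC content these were -0.11 and -0.05, and neither passed. The list median was -0.18 (camera, Benjamini-Hochberg adjusted p = 0.000461; adjusted p = 0.0944 with an estimated correlation, and 0.062 after correction for gene length and GC content). Of 15 factors for transcription, 3' processing and decay of histone mRNA, 4 fell, with a list median of -0.13 (camera, Benjamini-Hochberg adjusted p = 0.00818; adjusted p = 0.157 with an estimated correlation, and 0.108 among genes holding under 10% background). They included CPSF2 (-0.29), a subunit of the 3' cleavage complex, and SLBP, the protein that binds the histone mRNA stem-loop, which went from 112 ± 8.36 to 97.9 ± 3.38 CPM (log2 fold change -0.19; edgeR, Benjamini-Hochberg adjusted p = 0.0176). Of 12 pseudouridine synthase genes 4 fell, namely DKC1 (-0.26), RPUSD2 (-0.60), PUS10 (-0.45) and PUS7, and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.0678). PUS10 lost its call under 6 of 18 alternatives, 3 of them left-out libraries. PUS7 went from 191 ± 15.5 to 173 ± 7.78 CPM (log2 fold change -0.14; edgeR, Benjamini-Hochberg adjusted p = 0.045). The calls of PUS7 and SLBP both ended with scaling to library size alone (log2 fold changes -0.06 and -0.11) and with background subtracted (-0.10 and -0.14). That of PUS7 also ended with the replicate block (-0.14), and without control replicate 2 (-0.09) or tDR replicate 2, 3 or 4 (-0.13, -0.14 and -0.15), and that of SLBP after correction for length and GC content (-0.12) and without control replicate 4 (-0.16) or tDR replicate 4 (-0.18).

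Autophagy genes moved in both directions, and the list of 30 was not called (camera, Benjamini-Hochberg adjusted p = 0.712). The genes OPTN (0.65 on the log2 scale), SQSTM1, ATG2A (0.41) and ULK1 rose, and ATG3 (-0.42), TAX1BP1 and ATG12 fell. SQSTM1, which encodes the cargo receptor p62, went from 115 ± 4.11 to 146 ± 6.33 CPM (log2 fold change 0.35 ± 0.056, SE; edgeR, Benjamini-Hochberg adjusted p = 4e-06). MAP1LC3B, which encodes the autophagosome protein LC3B, stood at 45.9 ± 3.92 and 46.8 ± 0.866 CPM (log2 fold change 0.03; edgeR, Benjamini-Hochberg adjusted p = 0.812). Of 22 lysosomal genes 3 rose, NEU1 (0.57), MCOLN1 (0.46) and CTSL (0.24), and that list was not called either (camera, Benjamini-Hochberg adjusted p = 0.229). CTSL lost its call under 7 of 19 alternatives and MCOLN1 under 4 of 19. Targets of hypoxia-inducible factor split into 4 higher and 3 lower of 19, with NDRG1 at -0.31 and the glucose transporter gene SLC2A3 at 0.98 (camera, Benjamini-Hochberg adjusted p = 0.712).

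Inflammatory and stress genes included several of the larger increases. Of 6 tested NF-kB and cytokine genes 3 rose. These were RELB, which went from 3.26 ± 0.866 to 10.5 ± 1.61 CPM (log2 fold change 1.66), NFKB2 (0.63), which like RELB encodes a subunit of NF-kB, and TNFAIP2 (1.16), which lost its call under 7 of 18 alternatives, background subtraction among them. The list median was 0.89 (camera, Benjamini-Hochberg adjusted p = 0.00818; adjusted p = 0.0959 with an estimated correlation, 0.0702 with no filter on low counts and 0.0832 among genes under 10% background, where the median was 0.18). Among 10 immediate early genes 4 rose and 1 fell; EGR1 went from 3.07 ± 0.972 to 8.80 ± 1.31 CPM (log2 fold change 1.48), ATF3 rose by 0.73 and KLF10 by 0.52 (its call was lost under 4 of 19 alternatives), and MYC fell by 0.39 (camera, Benjamini-Hochberg adjusted p = 0.186). The integrated stress response list had 6 higher and 3 lower genes of 16, with ATF3, PPP1R15A (0.47) and SESN2 (0.35) among the higher and the serine synthesis gene PHGDH (-0.20) among the lower (camera, Benjamini-Hochberg adjusted p = 0.403). Of 15 targets of the unfolded protein response, SEL1L (0.20) and HERPUD1 (0.27) rose and PDIA6 (-0.16) fell (camera, Benjamini-Hochberg adjusted p = 0.471). HERPUD1 lost its call under 11 of 19 alternatives, among them 7 of the 8 left-out libraries, and SEL1L under 6 of 19. Of 17 p53 targets 2 rose, CDKN1A (0.67), the inhibitor of cyclin-dependent kinases, and SPATA18, and CCNG1 fell (camera, Benjamini-Hochberg adjusted p = 0.599). Among 15 oxidative stress genes HMOX1 (0.66) and FTL (0.41) rose and 4 fell, including TKT (-0.33) and TXN (-0.39) (camera, Benjamini-Hochberg adjusted p = 0.471). Of 15 apoptosis genes HRK (0.47) rose and CYCS (-0.33), the gene for cytochrome c, fell (camera, Benjamini-Hochberg adjusted p = 0.652). After correction for length and GC content CYCS was at -0.14. Of 14 interferon-stimulated genes MX1 (1.85), MX2 (1.49) and PARP9 (0.75) rose (camera, Benjamini-Hochberg adjusted p = 0.0893), but MX1 and MX2 were near the floor, at 0.599 ± 0.123 and 0.865 ± 0.123 CPM in controls, and an estimated 57.1% and 57.7% of their counts were background.

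Genes of growth and energy supply were lower as lists. The medians and counts of these lists rest on TMM scaling. With library size alone the median log2 fold change of all tested genes was 0.10 rather than 0.02, and 907 rather than 1962 genes were lower. Of 57 ribosomal protein genes 52 fell, with a median of -0.24 (camera, Benjamini-Hochberg adjusted p = 4.91e-19; adjusted p = 0.0944 with an estimated correlation); RPL24 went from 389 ± 17.4 to 287 ± 22.3 CPM and RPL6 from 860 ± 51.5 to 669 ± 24.3 CPM. After correction for gene length and GC content that median was -0.10. Of 24 nuclear genes of oxidative phosphorylation 15 fell, with a median of -0.21, among them COX4I1 (-0.26) and ATP5F1C (-0.30) (camera, Benjamini-Hochberg adjusted p = 1.8e-07; adjusted p = 0.0944 with an estimated correlation). After correction for length and GC content COX4I1 was at -0.11 and did not pass, and ATP5F1C was at -0.17. Of 23 G2/M genes 17 fell, with a median of -0.20, among them CENPF (-0.32) and CDC20 (-0.41) (camera, Benjamini-Hochberg adjusted p = 1.98e-08; adjusted p = 0.0944 with an estimated correlation). Of 27 G1/S and S phase genes 13 fell, with a median of -0.14, among them MCM6 (-0.36) (camera, Benjamini-Hochberg adjusted p = 0.000131; adjusted p = 0.157 with an estimated correlation). Of 20 aminoacyl-tRNA synthetase genes 13 fell, with a median of -0.18, among them EPRS1 (-0.30) and LARS1 (-0.28) (camera, Benjamini-Hochberg adjusted p = 2.63e-06; adjusted p = 0.0944 with an estimated correlation).

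Of 14 glycolytic enzymes 7 fell, with a median of -0.14, among them ENO1 (-0.30) and LDHA (-0.32, and -0.17 after correction for length and GC content) (camera, Benjamini-Hochberg adjusted p = 0.00022; adjusted p = 0.0959 with an estimated correlation). Of 21 cholesterol synthesis genes 5 fell, with a median of -0.13; SQLE, the squalene epoxidase gene, went from 202 ± 4.77 to 145 ± 9.80 CPM and FDFT1 fell by 0.28 (camera, Benjamini-Hochberg adjusted p = 0.00149; adjusted p = 0.0955 with an estimated correlation). Of 13 heat shock genes 8 fell, with a median of -0.23; HSPD1 went from 868 ± 46.8 to 633 ± 36.8 CPM and HSPA4 fell by 0.36 (camera, Benjamini-Hochberg adjusted p = 0.000569; adjusted p = 0.0959 with an estimated correlation, and 0.0727 after correction for length and GC content). Of the 13 mRNAs encoded in mitochondrial DNA 6 fell, among them MT-CO1 (-0.27) and MT-CO3 (-0.18), and the list median was -0.07 (camera, Benjamini-Hochberg adjusted p = 0.0086; adjusted p = 0.509 with an estimated correlation). That median turned to 0.02 with scaling to library size alone and to 0.16 after correction for length and GC content, so no direction is given for this list. After that correction MT-CO1 was at -0.05 and MT-CO3 at 0.05, and neither passed. Of 17 genes of tRNA fragment formation YBX1 (-0.22), QTRT2 and TRDMT1 fell and AGO1 (0.15) rose (camera, Benjamini-Hochberg adjusted p = 0.0893); AGO1 lost its call under 8 of 19 alternatives, 4 of them left-out libraries. Of 14 matrix genes 4 rose, including COL6A2 (0.46) and SPARC (0.33), and COL4A2 fell (camera, Benjamini-Hochberg adjusted p = 0.14). Of 8 kidney tubule and injury genes KRT8 (0.63), PAX2 (0.44) and CUBN rose (camera, Benjamini-Hochberg adjusted p = 0.283). Among 11 tested abundant short noncoding RNAs VTRNA1-3 (-0.65) and RNU1-1 fell and RNU4-1 rose (camera, Benjamini-Hochberg adjusted p = 0.599); 8 others, such as RN7SK and RN7SL1, were at 0 counts in all 8 libraries. These RNAs are abundant in most cells and the treatment of reads that fit several places is not given in the sources used here, so the 0 counts set no limit on their level.

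**Figure D3:**
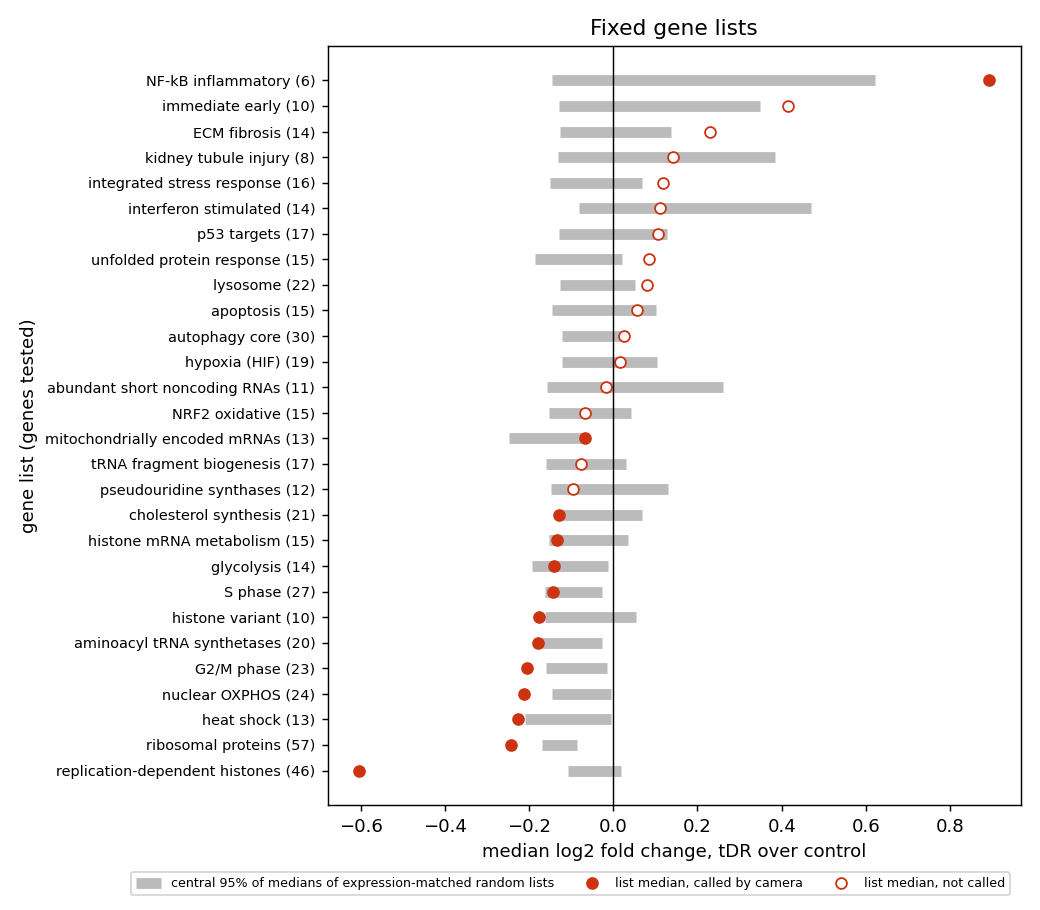
Median log2 fold change, tDR over control, of each fixed gene list (points, filled where camera called the list with its preset correlation) beside the central 95% of medians of 10000 random lists with the same expression levels (bars). The histone median of -0.60 lies far to the left of its bar, which runs from -0.11 to 0.02; no list was called with an estimated correlation, and the mitochondrially encoded list changes sign with the scaling.

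In these libraries abundant genes had lower fold changes than rare ones, so each list was also set beside random lists with the same expression levels. Of the 11 lists called lower besides the histone list, 7 had a median below the central 95% of their random lists: histone variants, G2/M, ribosomal proteins, aminoacyl-tRNA synthetases, oxidative phosphorylation, cholesterol synthesis and heat shock. The medians of S phase, glycolysis and histone mRNA metabolism lay at percentiles 7.74, 22 and 5.65, and that of mRNAs encoded in mitochondrial DNA at 97.94, above its random lists although camera called it lower. On the other side, the medians of NF-kB, autophagy, lysosome, the integrated stress response, the unfolded protein response, matrix and immediate early genes lay above the central 95% of their random lists, at percentiles 99.93, 98.68, 99.42, 99.63, 99.95, 99.8 and 98.93. Of these 7 lists camera called only NF-kB.

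Among single genes outside those lists, NEAT1 (chromosome 11, 65422774 to 65445540) went from 103 ± 12.2 to 185 ± 18.1 CPM (SD, n = 4), a log2 fold change of 0.84 ± 0.064 (SE; edgeR, Benjamini-Hochberg adjusted p = 9.13e-16). The U6 small nuclear RNA copy RNU6-2 (chromosome 19, 1021522 to 1021628) went from 0.489 ± 0.207 to 8.42 ± 1.71 CPM, a log2 fold change of 4.02 ± 0.34 (SE; edgeR, Benjamini-Hochberg adjusted p = 2.98e-14); U6 has near-identical copies, so the copy is uncertain, and the control level was near the floor, so the size of the change is uncertain too. MKNK2, a kinase gene of the pathway that phosphorylates eIF4E, went from 68.8 ± 4.16 to 103 ± 5.28 CPM (log2 fold change 0.58). ETV5, an ETS family transcription factor gene, rose by 1.85 ± 0.26 (SE) on the log2 scale, to 7.69 ± 1.34 CPM, and LINC02325 rose by 1.5 with 49.7% estimated background. In the other direction AMOT, the angiomotin gene, went from 1545 ± 57.7 to 1053 ± 31.1 CPM, a log2 fold change of -0.55 ± 0.041 (SE; edgeR, Benjamini-Hochberg adjusted p = 4.39e-16). MT2A, a metallothionein gene, fell by 0.91, THAP9 by 0.86 and HSBP1 by 0.79 on the log2 scale. Changes over 2-fold were mostly increases, with 598 genes higher and 11 lower. Genes of low expression were shifted up as a group. Their median log2 fold change was 0.45 up to a mean log2 CPM of 1 and 0.31 from there to 3. The excess of large increases cannot be told apart from that shift.

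Several of the increases with the smallest p were in long genes. DPP6, PTPRT, RBFOX1, PTPRN2, RGS6, LRMDA and LINC01411 were among the 10 increases with the smallest p, with log2 fold changes of 1.07, 1.07, 0.85, 0.90, 1.2, 0.79 and 1.4. Counts over olfactory receptor genes, which most tissues do not express, gave a measure of background. Their density was 0.0152 ± 0.00196 CPM per kb in controls and 0.0250 ± 0.00119 with the tDR (SD, n = 4; ratio 1.64; exact two-sided permutation p = 0.0286, the smallest that 70 assignments can give). Spread over whole gene spans, this density would account for 59.9% of the counts of DPP6, 80.3% of those of RBFOX1 and 27.0% of those of LINC01411. Of 2147 tested genes with over 50% estimated background, 870 were higher and 1 lower. Among genes with under 10%, 722 were higher and 1942 lower, and 994 and 1166 when these genes were scaled and tested by themselves. With background subtracted, 2164 genes passed, 1075 higher and 1089 lower, and DPP6, PTPRT, RBFOX1, PTPRN2, RGS6, LRMDA and LINC01411 still passed, with log2 fold changes of 1.86, 2.51, 1.89, 1.36, 2.40, 0.96 and 1.78. These are ratios over what subtraction leaves of the control counts. After correction for length and GC content they passed with smaller values of 0.76, 0.75, 0.46, 0.56, 0.93, 0.50 and 1.26, so the size of these increases depends on the processing.

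**Figure D4:**
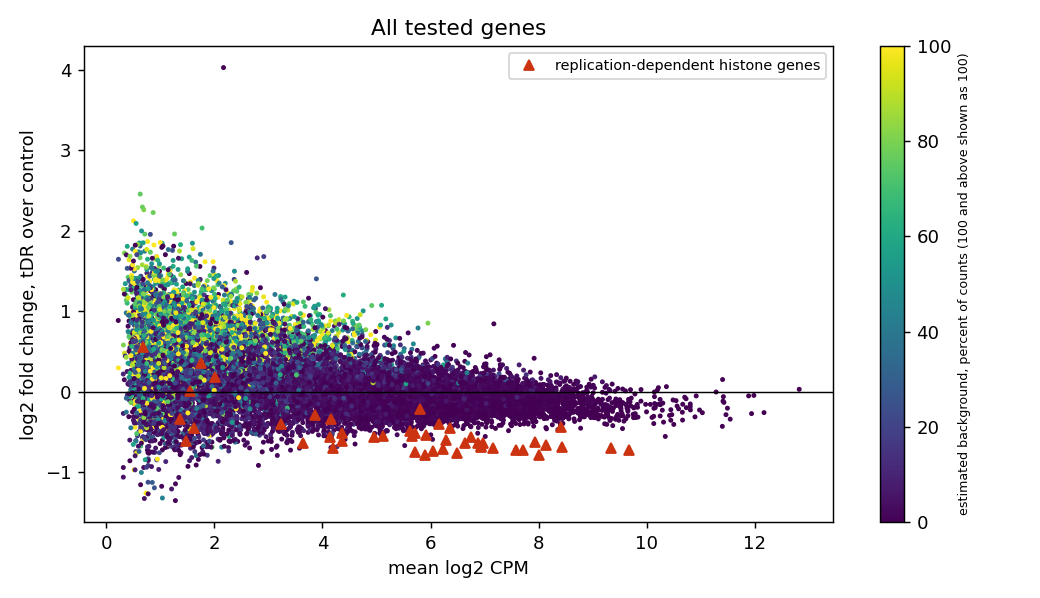
Log2 fold change, tDR over control, against mean log2 CPM for all 17184 tested genes, coloured by the share of counts that a uniform background would give. Triangles mark replication-dependent histone genes; genes with a high share of background (light colours) lie at low expression and mostly above 0, with 870 higher and 1 lower among the 2147 genes over 50%.

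Markers of other cell types were tested as well. Of 4 tested fibroblast genes COL1A1 (0.66) and PDGFRB rose, of 8 endothelial genes PECAM1 (1.63) and CDH5 rose, of 2 epithelial genes CDH1 (0.62) rose, and the single tested hepatocyte gene, TTR (0.92), rose. CDH1 lost its call under 12 of 18 alternatives and TTR under 11 of 18, background subtraction among them. The median estimated background of these lists was 15.7%, 54.0%, 39.6% and 34.1%. The single tested blood gene, PTPRC, stood at 2.53 ± 0.985 and 3.52 ± 0.777 CPM and did not pass. Of 6 neural genes, the neurofilament genes NEFM (-0.41) and NEFL (-0.46) fell, from 230 ± 17.4 and 112 ± 4.91 CPM in controls. Mitochondrial counts made up 3.44% ± 0.210 of control and 3.47% ± 0.0993 of tDR libraries (SD, n = 4), and ribosomal RNA 0.0538% ± 0.0137 and 0.0543% ± 0.00700. Over these measures, total counts, genes detected, and the shares of short noncoding RNA and of the 10 most abundant genes, the smallest exact permutation p was 0.0571 (0.257 after Benjamini-Hochberg adjustment).

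Scaling to library size alone left 4202 genes past the threshold but split them into 3295 higher and 907 lower, and DESeq2 called 1441 higher and 2184 lower. A minimum fold of 1.2 left 833 genes, 740 higher and 93 lower.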

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

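Apart from the count of changed genes over other splits of the libraries, the tests of explanations in this part were chosen after the results were seen. A library stood apart from the other 3 of its group where its gap to the nearest, divided by the group's range, was above Dixon's critical value for 4 values. That happened for 23 of the 216 groups of 4 values tested, where chance gives about 10.8, and 10 of the 23 were tDR replicate 1, the library with the fewest counts.

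In tDR replicate 1 the histone share was 0.438% against 0.407% to 0.411% in the other 3 (ratio of gap to range 0.880). H1-4 stood at 671 CPM against 589 to 599 (0.873), H4C3 at 114 against 85.0 to 88.8 (0.873), H4C2 at 43.5 against 36.4 to 37.3 (0.874) and SLBP at 103 against 95.8 to 96.5 (0.904). Its top 10 genes held 3.84% of counts against 3.60% to 3.63% (0.876). TNFAIP2 stood at 4.40 CPM against 1.68 to 2.05 (0.864), CDH1 at 4.06 against 7.39 to 7.94 (0.857), LRMDA at 58.1 against 71.6 to 72.8 (0.918) and PTPRT at 34.7 against 41.9 to 43.2 (0.856). Without this library the histone median was -0.68 and 4153 genes passed.

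The remaining 13 were spread over the other 7 libraries. In control replicate 1, CDC20 stood at 82.3 CPM against 104 to 108 (0.849), RPL6 at 938 against 834 to 836 (0.982), YBX1 at 1637 against 1444 to 1464 (0.898), HSPD1 at 938 against 838 to 850 (0.878) and H4C2 at 72.5 against 61.2 to 62.6 (0.871). In control replicate 2, PUS7 stood at 214 CPM against 181 to 186 (0.851) and ETV5 at 2.57 against 1.91 to 1.97 (0.904). SPARC stood at 35.3 CPM in control replicate 3 against 41.3 to 42.2 (0.861), and NFKB2 at 13.9 in control replicate 4 against at most 17.2 in the other controls (0.943). H2BC4 stood at 142 CPM in tDR replicate 2 against 161 to 162 (0.978), TTR at 4.79 in tDR replicate 3 against 2.62 to 2.88 (0.882), MCOLN1 at 13.3 in tDR replicate 4 against 17.1 to 17.8 (0.843), and short noncoding RNA at 0.298% of counts in tDR replicate 4 against 0.322% to 0.327% (0.832).

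For the lower histone mRNA, only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave a median as far from 0 (0.603, highest other 0.435). A grouping by chance is argued against as far as 35 splits allow. Camera with the preset correlation called the list in 17 of the other splits. Nearly all of these kept 3 libraries of a group together and so part of the group difference. Among splits with 2 libraries of each group on each side, camera called the list only with control replicates 1 and 2 beside tDR replicates 2 and 4 (Benjamini-Hochberg adjusted p = 0.0254). Loss of short unspliced transcripts in library preparation was tested with 72 single-exon genes under 3 kb outside the histone families. Their median log2 fold change was -0.14 (95% bootstrap interval -0.19 to -0.06), while 33 single-exon histone genes had -0.61. That argues against a loss shared by all such transcripts as the whole cause. The 72 genes were matched on exon number and a span limit only. Histone genes such as H2AC20 (390 bp) and H3C2 (411 bp) lie far below that limit, so a loss limited to shorter transcripts cannot be excluded. Reads moving between counted near-identical copies are argued against by the change of the summed share, -32.5% (exact permutation p = 0.0286, the smallest possible). If reads that fit several copies were left out of the counts, more such reads with the tDR would lower the sum itself. Their treatment is not given, so the test does not cover that case. Fewer cells in S phase cannot be told apart from an effect on histone mRNA itself: the S phase list lay below its expression-matched random lists by a difference of -0.0502, at percentile 7.74, and cell cycle was not measured, so both stay open as hypotheses beside the transfected tDR.

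Count density over olfactory receptor genes was 1.64 times as high with the tDR as in controls, where it ran from 0.0136 to 0.0179 CPM per kb. A uniform background over genes may account for the higher counts of long and silent genes, but the test cannot decide. It used 186 genes over 500 kb with over 50% estimated background, called silent here. DPP6, PTPRT and RBFOX1 meet these limits and still passed with background subtracted, so not all such genes are silent. In the 186 genes the density added with the tDR was 1.04 times that added in olfactory receptor genes. The 95% bootstrap interval, 0.747 to 1.49, is wide and reaches past the bounds of 0.7 to 1.4 that were set for the test. Selection by this background ties the genes' density to that of olfactory receptor genes, so a ratio near 1 is partly built in. More pre-mRNA of expressed genes stays open: across genes Spearman's rho between span and log2 fold change was 0.267 before subtraction and 0.0308 after it in 11332 genes under 10% background (95% bootstrap interval 0.0106 to 0.0487; genes are not independent replicates), but subtraction takes away a term that grows with span, so the low value excludes nothing. DNA in the RNA samples and RNA from silent regions would both give a uniform background, and no value here separates them. The number of changed genes itself was not matched by another split: 4168 in the real one, 0 as the highest of the others, with 1 of 35 as large. The other splits mix the groups on each side, which adds the group difference to the spread within a side. Low counts there are thus likely for any difference between the groups, and the cause of the difference is not tested by it.

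The lower ribosomal protein mRNAs were weighed against 3 trends that run through the table. The trend with expression level is argued against as the whole cause, since the list median lay below its matched random lists by a difference of -0.11, with 0 of 10000 random lists as low. After correction for length and GC content the median was -0.10 (camera at the preset correlation, Benjamini-Hochberg adjusted p = 2.76e-06). With background subtracted it was -0.19 (camera, Benjamini-Hochberg adjusted p = 1.08e-18). Neither trend taken alone accounts for all of it, although the first took away the larger part of the -0.24 seen before. The 3 trends were not removed together, and the matched random lists already had a median of -0.13, so a joint cause is not excluded. With an estimated correlation 0 of the other lists were called. The number of other lists called, 12, was also reached by another split (2 of 35 splits called as many, highest other 12), so this test cannot exclude chance for that number. That other split set control replicate 1 with tDR replicates 1, 2 and 4 and so kept part of the group difference. Splits with 2 libraries of each group on each side called 0 to 2 lists. A response of growth genes to the tDR stays open as a hypothesis.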

How the results depend on the processing

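The alternatives named here were fixed in advance, except background subtraction and the limit to genes under 10% background, which were chosen after seeing the data. The number of changed genes stayed within 1.5 times 4168 under 19 of 22 alternatives (3162 to 4309 when a library was left out). It was 2164 with background subtracted (2057 of the 4168 kept, 2 turned), 2160 among genes under 10% background, where 11816 genes were tested (1888 kept of the 2664 called genes among them), and 833 with a minimum fold of 1.2, a stricter question. Which genes passed was less stable than how many. Length and GC correction kept the call and direction of 2692 of the 4073 called genes it covered, and 7 turned. Library size alone kept 3113 of the 4168. The median of the 17184 genes left by the filter was 0.02 with TMM, 0.006 with DESeq2's size factors and 0.10 with library size alone. DESeq2 itself was run without that filter, so its median of 0.11 covers more genes of low expression. Its calls were 39.8% higher against 52.9% with TMM. Without the filter TMM gave a median of 0.09, with 44.2% of calls higher. The histone median kept its direction and call under 20 of 21 alternatives (-0.63 to -0.40; -0.68 to -0.57 with a library left out); with an estimated correlation it was -0.60 with an adjusted p of 0.0944, against a range of 2.05e-30 to 0.0944 over its alternatives. The 5 histone classes kept theirs under the 18 alternatives with a preset correlation and lost them with an estimated one (lowest adjusted p 0.0944). The number of other lists called was 12, but 0 with an estimated correlation and 19 with fry, which tests another question; leaving out a library gave 12 to 15.

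The replicate numbers did not pair the libraries: the correlations of same-numbered deviations were -0.0103, 0.0699, -0.0287 and 0.0192, and only replicate 2 correlated best with its own number. With the replicate block 3874 genes passed, the calls of PUS7, HERPUD1, CDH1 and TTR ended, and the paired histone share difference of -0.201 percentage points had an exact sign-flip p of 0.125, the smallest that 4 pairs can give.

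Of the 98 called genes that are named by the rule with values, 74 kept their call and direction under each alternative run for single genes. Those alternatives left out the minimum fold, limma voom and the adjusted p under 0.1. Of 1841 values, 1724 kept both, 115 lost the call and 2 turned. Called genes named without a value, such as ULK1, SPATA18 and CUBN, are not part of these counts. MT-CO3 turned to 0.0542 with length and GC correction and to 0.0550 with the block added; the cause was not tested. Of the other named genes, MAP1LC3B turned to -0.000976 with no filter and -0.000296 in DESeq2 (-0.0189 to 0.0812 with a library left out), and PTPRC to -0.0751 with background subtracted; the cause was not tested. Calls ended without control replicate 1 for MCOLN1, TNFAIP2, HERPUD1, CDH1 and THAP9; without control 2 for PUS10, PUS7 and HERPUD1; without control 3 for CTSL, TNFAIP2, SEL1L, CDH1 and TTR; without control 4 for SLBP, PUS10, CTSL, TNFAIP2, SEL1L, HERPUD1, AGO1, KLF10, CDH1 and TTR; without tDR 1 for CTSL, TNFAIP2, SEL1L, HERPUD1, AGO1, KLF10 and TTR; without tDR 2 for PUS10, PUS7, MCOLN1, SEL1L, HERPUD1, AGO1, HRK, KRT8, CDH1 and TTR; without tDR 3 for PUS7, MCOLN1, CTSL, HERPUD1, CDH1 and TTR; without tDR 4 for SLBP, PUS7, CTSL, HERPUD1, AGO1, KLF10, CDH1 and TTR. Length and GC correction ended those of H2AZ1, H3-3B, SLBP, PUS10, AGO1, COX4I1, MT-CO1, PAX2, CDH1 and THAP9, library size alone those of H3-3B, SLBP, PUS10, PUS7, PHGDH, PDIA6 and MT-CO3, no filter those of CTSL, TNFAIP2, SEL1L, HERPUD1, AGO1, CDH1 and TTR, DESeq2 those of the same 7, MCOLN1 and KLF10, DESeq2's size factors that of HERPUD1, the limit to genes under 10% background those of H3-3B, SLBP, PUS7 and PDIA6, and background subtraction those of H3-3B, SLBP, PUS7, TNFAIP2, MX2, PDIA6, CDH1 and TTR. Length and GC correction also made values over 1.5 times smaller without ending the call: H4C3 -0.45, CPSF2 -0.19, DKC1 -0.15, ATG3 -0.27, LDHA -0.17, RPL24 -0.25, RPL6 -0.20, ATP5F1C -0.17, TXN -0.23, CYCS -0.14, VTRNA1-3 -0.38, NEFL -0.30, LRMDA 0.50, RBFOX1 0.46 and PTPRN2 0.56. Other alternatives took the log2 fold changes of MX1, MX2, PECAM1 and LINC02325 as high as 6.34, 3.02, 3.59 and 2.75, so the size of these increases depends on the processing. At these depths 50% of 50 simulated 1.3-fold changes were recovered, so changes of that size can be missed.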

Other observations

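The gene families in this part were chosen after the data were seen, by the shared start of gene symbols over 139 families, and tested with camera adjusted over those families. Genes for mitochondrial ribosomal proteins, which translate the mRNAs of mitochondrial DNA, fell alongside those of cytosolic ribosomes: 27 of 43 MRPL genes fell, with a median log2 fold change of -0.24 (camera, Benjamini-Hochberg adjusted p = 6.45e-10; adjusted p = 0.0935 with an estimated correlation), and 10 of 22 MRPS genes, with a median of -0.20 (adjusted p = 2.6e-05, and 0.0935 with an estimated correlation). Of 54 EIF genes, most of which encode translation initiation factors, 29 fell and 1 rose, with a median of -0.20 (adjusted p = 1.02e-08, and 0.0935 with an estimated correlation). Of 13 IFT genes, which encode proteins that carry cargo along cilia, 8 fell, with a median of -0.27 (adjusted p = 0.000227, and 0.0935 with an estimated correlation). With background subtracted these 4 medians were -0.19, -0.17, -0.15 and -0.25.

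In the other direction 9 of 13 CACNA genes, which encode subunits of voltage-gated calcium channels, rose, with a median of 0.59 (camera, Benjamini-Hochberg adjusted p = 0.000243; adjusted p = 0.104 with an estimated correlation). Their median estimated background was 23.4%, and with background subtracted the median was 0.60. Of 657 LINC genes, long intergenic noncoding RNAs, 204 rose and 8 fell, with a median of 0.51 (camera, Benjamini-Hochberg adjusted p = 1.28e-10; adjusted p = 0.104 with an estimated correlation). Their median background was 38.1%, and with background subtracted the median was 0.31 (adjusted p = 0.00454 at the preset correlation).

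Fold changes also followed GC content. Across 11332 genes under 10% background, Spearman's rho between GC content and background-subtracted log2 fold change was 0.269, across genes, which are not independent replicates. The median was -0.08 in 1844 genes with a GC content of up to 40% and 0.09 in 1621 genes above 60%. Over the same genes rho with mean log2 CPM was -0.175.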
